A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

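The series holds 11 libraries of Saccharomyces cerevisiae RNA: 2 S288C TL-seq libraries described as biological replicates, 1 Sigma 1278b TL-seq library with and 1 without pyrophosphatase, and 7 TATL-seq libraries, 1 per polysome gradient fraction, labelled BY4742. Per the labels' protocols, cells were grown to mid-log phase in rich medium, RNA was poly(A)-selected and fragmented with alkali, and free 5′ phosphates were removed with calf intestinal phosphatase. Fragments were then treated with tobacco acid pyrophosphatase, or mock-treated in the control, and ligated to a 5′ adaptor, so that reads should begin at former caps. The 3′ end was captured by poly(A) tailing in TL-seq and by adaptor ligation in TATL-seq, per the labels' protocols. The same protocols name a HiSeq 2000 for the S288C TL-seq libraries and a Genome Analyzer II for all others. The submitters' processing notes name Bowtie for every library, without a version, and the genome build sacCer3 for the 9 libraries of the Genome Analyzer II. The build for the S288C TL-seq libraries, the annotation and the rule that turned reads into 1 length per gene are not given in the sources used here. Whether a leader length counts introns that lie before the start codon is therefore unknown.

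Each deposited file lists a gene and 1 leader length in nucleotides (nt), as the authors called it, with no reads, depth or header. A length is not an abundance, so no expression or gradient distribution was computed, and the planned count tests and the alternatives for read minimums or several leaders per gene did not apply. Absence from a file was taken as no call, which can reflect low expression, depth or the authors' filters. No intervals from read counts can be given; intervals on shares cover counting error over ORFs only, and ORFs are not independent replicates. Intervals are at 95%, Wilson for shares of ORFs by length and exact Clopper-Pearson for shares called per fraction, per list (over members called in any library) and in the control.

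All 4551 ORF names matched locus tags of the RefSeq gene table of assembly R64, which gave symbols, neighbours, positions of ORFs and lengths; these lengths are genomic spans that include introns (96.3% are multiples of 3), and they stand in for the coding length that was planned. The 57 snoRNA and tRNA names were kept out of the comparisons. Leaders in upstream AUG classes were planned but not analysed here, since no genome sequence was used.

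Before the data were examined, the samples were grouped by their labels, and the tests, thresholds, alternatives, 15 gene lists and rule for naming genes were fixed. An ORF counted as different between Sigma and S288C when the S288C replicates lay within 10 nt of each other and Sigma lay at least 10 nt from both on the same side. The TATL-seq length of an ORF was its median over the fractions with a call. Range over fractions used ORFs called in at least 5 of 7. Trends used Spearman correlation with fraction number and all 5040 orders of the 7 fractions. Short leaders were under 12 nt by the mean of the S288C replicates and were tested per fraction by Fisher's exact test, two-sided. Benjamini-Hochberg adjustment was made over each family of tests with a threshold of 0.05.

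The named ORFs were the 10 most lengthened and 10 most shortened in Sigma, the 10 with the widest range over fractions, the 10 longest and 10 shortest S288C leaders (all with replicates within 10 nt where these are used), up to 20 called without pyrophosphatase in alphabetical order, and up to 4 members of each list per comparison. For agreement between TL-seq and TATL-seq, the ORFs named other than glycolysis genes were chosen after their values were seen. So were the ribosomal protein genes named in the control, and the members of the mating-type groups beyond that rule. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis and fermentation, translation factors, genes with characterised upstream ORFs, genes with long leaders in earlier work, genes with alternative start sites, heat shock and stress, respiration, histones, proteasome, a-specific genes, α-specific genes, auxotrophic markers of the growth protocol, and invasive growth and cell surface with strain difference, called invasive growth below. The tests of list lengths (rank permutation with 100000 draws, lists of at least 10 ORFs) and of lists in the pyrophosphatase control were added after first values had been seen.

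The scripts were tested on simulated data. For Sigma against S288C, the lengths of 1492 ORFs were given noise drawn from replicate differences over the 3144 ORFs called in both replicates. Shifts of 15 nt were called in 86.5% of eligible ORFs and those of 40 and 100 nt in 100%. Those of 6 nt were called in 6.98%. With no shift 81 of 1126 were called longer and 76 shorter. For the trend over fractions, 200 of 200 rising ORFs of 800 were recovered with 12 false calls among 600, which holds for trends shared by many ORFs and not for a trend in 1 ORF. The simulated rising ORFs had few ties in length, unlike the tested ORFs of the data. The chance number of trends and the joint reordering of fractions were added after the trend counts had been seen. For short leaders, a fraction with a lowered share among 3000 ORFs was recovered (Fisher's exact test, adjusted p = 6.14e-14) with 0 other fractions past the threshold. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.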

Results

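Transcript leaders, the part of an mRNA between its capped 5′ end and its start codon, were mapped in budding yeast by TL-seq, which sequences capped 5′ ends. TL-seq was made from 2 biological replicates of S288C, the reference laboratory strain, and from 1 culture of Sigma 1278b, a strain used to study filamentous growth. A further Sigma library without tobacco acid pyrophosphatase, the enzyme that removes the cap so that the adaptor can be ligated, served as the control for uncapped ends. TATL-seq applied the method to 7 fractions of a polysome gradient, in which mRNAs sediment according to their ribosomes, from cells labelled BY4742, an S288C derivative of mating type α. The 11 libraries held 26043 leader calls on 4551 ORFs, 23 snoRNAs and 34 tRNAs, 1 length per gene and library. ORF calls numbered 3561 and 3442 in the S288C replicates, 1883 in Sigma with pyrophosphatase, 204 in Sigma without it, and 2081, 2412, 2483, 2471, 2446, 2480 and 2442 in fractions 1 to 7. The read depth behind a call is unknown, because the files give lengths and no counts. Per the labels, the S288C TL-seq libraries were sequenced on a HiSeq 2000 and all 9 others on a Genome Analyzer II, so sequencer and strain cannot be told apart in TL-seq.

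The S288C replicates gave the length of each leader and its replicate error. Median leaders were 42 nt and 43 nt long, and the 3144 ORFs called in both had a median of 41.5 nt (quartiles 24.5 and 70 nt). Of these, 240 (7.63%) were under 12 nt and 476 (15.1%) reached 100 nt. MRX16 had the longest leader at 1231 nt, followed by the thiamine transporter gene THI72 (1118 nt ± 4.24, SD, n = 2), the vacuolar gene VAC7 (1118 nt ± 0), THI22 (1035 nt ± 0), the 14-3-3 protein gene BMH2 (893 nt ± 0) and ICS2 (830 nt ± 0). The phosphate regulator PHO81 had 793 nt, AAD4 723 nt, VEL1 668 nt and BSP1 628 nt, each the same in both replicates. At the other end, 10 named ORFs had leaders of 1 nt in both replicates: AIM18, the anaphase-promoting complex subunit APC11, APM2, BET5, CAB5, CIN4, the splicing factor CLF1, the coenzyme Q gene COQ9, the kinetochore gene DAD4 and the spindle-positioning gene KAR9. This is the lowest length in these libraries, and further ORFs, such as PEX22 and SEC18, share it, so the 10 are the first by name. In Sigma, BET5, CAB5 and COQ9 had 42, 35 and 18 nt and CLF1 0 nt, and the rest of the 10 had no call. Replicates gave the same length for 2397 ORFs (76.2%) and lay within 10 nt of each other for 88.1% (95% Wilson interval 86.9 to 89.2). The SD of their difference was 15.4 nt, and 407 ORFs differed by 10 nt or more.

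Ribosomal protein genes had short leaders, with a median of 24 nt over 118 members (quartiles 20 and 32 nt) against 43 nt over the other 3026 ORFs. In S288C TL-seq only RPS21A, at 9 nt, was under 12 nt, and RPL1A had 13 nt. At the long end of the group RPS22B had 601 nt and RPS25B 469 nt, where it is not known whether introns are counted. The difference passed a two-sided permutation test over genes (p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 9e-05 over 9 lists). The medians were 19 nt against 34 nt in Sigma (n = 94, adjusted p = 5e-05 over 5 lists, permutation test). They were 17 nt against 40 nt in TATL-seq (n = 126, adjusted p = 9e-05 over 9 lists, permutation test). Under 12 nt were 15 of the 94 members in Sigma and 28 of the 126 in TATL-seq, where RPS21A had 15 nt. Genes with characterised upstream ORFs, short reading frames within leaders, had a median of 136.5 nt over 10 members, but the test did not pass after adjustment (permutation p = 0.0206, adjusted p = 0.0928). In this group the amino acid starvation regulator GCN4 had 572 and 567 nt in the replicates, the polyamine transporter gene HOL1 458 nt in both, SCO1 17 and 15 nt and DCD1 7 and 1 nt.

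The other lists with at least 10 members did not pass. Genes of mitochondrial ribosomal proteins had a median of 37.5 nt (n = 40, adjusted permutation p = 0.28), from MRPL13 at 5 nt to MRPL7 at 143 nt. Heat shock and stress genes had 55.5 nt (n = 14, adjusted permutation p = 0.28), with YDJ1, a co-chaperone, at 194 nt and SSB2, a ribosome-bound chaperone, at 24 nt. Respiration genes had 54 nt (n = 16, adjusted permutation p = 0.28), with the succinate dehydrogenase gene SDH1 at 153 nt and ATP15 at 22 nt. Histone genes had 31 nt (n = 11, adjusted permutation p = 0.501), proteasome genes 36.5 nt (n = 24, adjusted permutation p = 0.688), and translation factors and glycolysis and fermentation genes 38 nt each (n = 22 and n = 15, both adjusted permutation p = 0.741). Among these, the poly(A)-binding protein gene PAB1 had 143 nt, TIF4632, for the scaffold eIF4G2, 170 and 171 nt, and the phosphofructokinase gene PFK1 234 nt. Smaller lists were not tested. Genes described with long leaders in earlier work had a median of 140 nt (n = 6), with the cyclin gene CLN3 at 322 nt and GCN4 at the long end, but HSP26 at 75 nt and TIF4631, for the scaffold eIF4G1, at 32 nt, below the median of all ORFs. Of the genes with alternative start sites, the tRNA synthetase genes ALA1 and GRS1 had 107 and 165 nt. In the invasive growth list, which also holds genes of the cell surface and of strain difference, HAP1 and SOK2 had 292 and 225 nt and TEC1 34 nt.

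**Figure D1:**
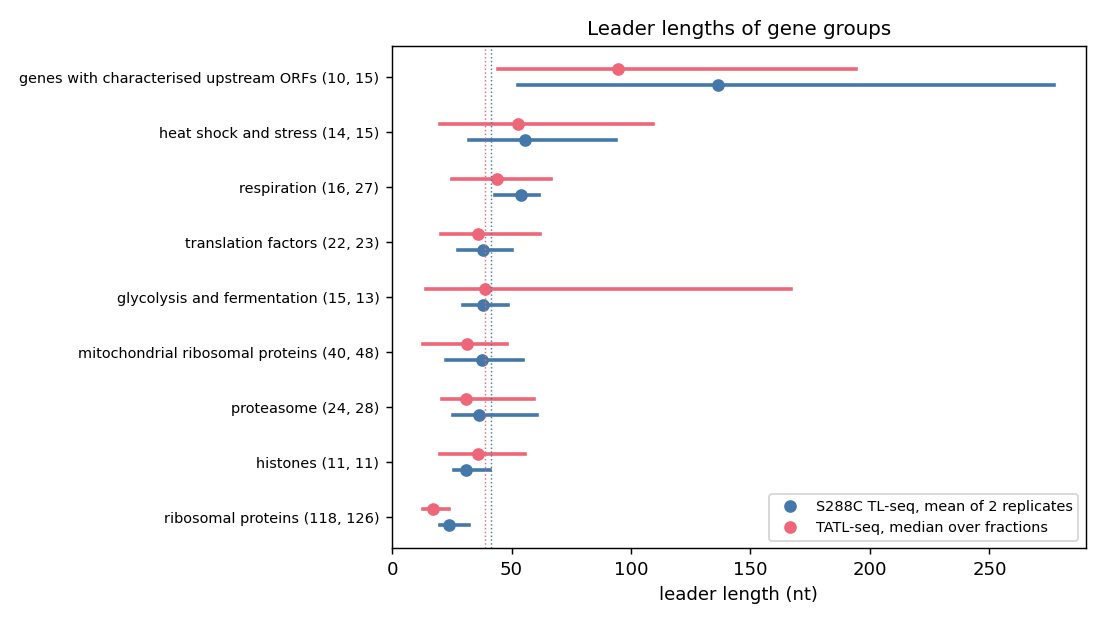
Median leader length in nt (points) and quartiles (bars) of each gene list with at least 10 ORFs in the S288C replicates, for S288C TL-seq (blue) and the TATL-seq median over fractions (red), with the numbers of ORFs in brackets in that order. Dotted lines mark the median of the ORFs outside a list, taken as the middle value over the lists. Ribosomal proteins had medians of 24 and 17 nt, against 136.5 and 94.5 nt in genes with characterised upstream ORFs.

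Sigma was set against S288C to ask whether leaders differ between strains. Of 1324 ORFs with S288C replicates within 10 nt of each other, 541 (40.9%, 95% Wilson interval 38.2 to 43.5) had a Sigma leader at least 10 nt from both replicates, 175 longer and 366 shorter. Ribosomal protein genes gave both kinds. RPL24B (chromosome VII, 787312 to 787779 in assembly R64) went from 30 nt to 430 nt and RPS25A from 35 nt to 351 nt. Their TATL-seq medians were 406 and 351 nt, and here too it is not known whether introns are counted. The proteasome ATPase gene RPT3 went from 105 nt to 3 nt. GPC1, the next gene to RPL24B (chromosome VII, 789031 to 790329), went from 353 nt ± 2.83 (SD, n = 2) to 49 nt. The SD between S288C replicates was at most 2.83 nt for each of the 20 ORFs with the largest differences. These were picked among ORFs with replicates within 10 nt of each other, so that SD was limited in advance.

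The other ORFs with much longer leaders in Sigma were PKR1 (29 nt to 621 nt), the proteinase inhibitor gene PBI2 (67 to 413 nt), the mitophagy gene ATG33 (59 to 346 nt), ECM3 (28.5 to 193 nt), APA2 (5.5 to 130 nt), YHL026C (66 to 186 nt), APT2 (42 to 149 nt) and the mitotic exit gene MOB1 (17 to 105 nt). Those with much shorter leaders were YRO2 (315 nt to 2 nt), the kinetochore gene CTF19 (179 to 31 nt), YML018C (132 to 6 nt), YGR026W (132 to 9 nt), AIM7 (129 to 11 nt), MRX21 (104 to 0 nt), the ribonuclease H gene RNH1 (116 to 16 nt) and the karyogamy gene PRM3 (223 to 130 nt). Over all differing ORFs with a TATL-seq call, the TATL-seq median was nearer to Sigma in 384 of 526 (73.0%), as for RPT3 at 3 nt and PBI2 at 413 nt. PKR1, ATG33 and YHL026C, with TATL-seq medians of 16, 60.5 and 66 nt, YML018C, with 133 nt, and PRM3, with 208 nt, lay nearer to S288C TL-seq. The TATL-seq length of YHL026C came from 1 fraction. In the Sigma library without pyrophosphatase PKR1 had 5 nt, far from its 621 nt, whereas YGR026W had 9 nt there too.

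By list, 8 of 85 ribosomal protein genes were longer and 19 shorter in Sigma, whereas against the TATL-seq medians the excess turned, with 10 of 94 longer and 2 shorter. Of the translation factors, 4 of 13 were shorter and none longer, and against TATL-seq 4 of 17 and none; the start-codon selection factor gene SUI1 went from 34 to 2 nt and TIF11 from 26 to 3 nt. Heat shock genes gave 3 shorter of 6, against TATL-seq 1 of 7, among them the ubiquitin gene UBI4 (112 to 83 nt) and SSA2 (39 to 15 nt). Mitochondrial ribosomal proteins gave 3 longer and 5 shorter of 20 (against TATL-seq 3 and 4 of 28), proteasome genes 2 and 3 of 11 (1 and 2 of 15), and respiration genes 1 and 2 of 7 (1 and 1 of 12). Against S288C TL-seq but not against TATL-seq, 1 of 6 histone genes was longer, the variant HTZ1 (85 to 102 nt), and 1 of 2 glycolysis genes shorter, the minor pyruvate kinase gene PYK2 (99.5 to 13 nt). Of the genes with earlier long leaders 1 of 3 was shorter, the small heat shock protein gene HSP26 (75 to 63 nt), and against TATL-seq 1 of 4. None of 3 genes with characterised upstream ORFs passed the rule, against TATL-seq 1 of 6 was shorter, and TEC1, the 1 invasive growth gene compared, was longer against TATL-seq only (41 and 31 nt). No alternative-start, mating-type or marker gene could be compared with S288C TL-seq, and none of 1 alternative-start and 3 a-specific genes differed from TATL-seq.

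A single Sigma library allows no test of a gene. In the ORFs called in all 3 libraries the replicates themselves differed by 10 nt or more in 178 of 1492 (11.9%). Simulated ORFs with replicate noise and no shift passed the rule in 157 of 1126 (13.9%). That noise came from S288C replicates of the same sequencer and held no median shift. The simulated share may thus be too low for a comparison across sequencers. On the Genome Analyzer II alone, Sigma against the TATL-seq medians gave 355 differing ORFs of 1789, 187 longer and 168 shorter; after the median difference of −4.5 nt between Sigma and S288C TL-seq was subtracted, 497 differed, 239 longer and 258 shorter. The share shorter in Sigma was 67.7% of differing ORFs against S288C TL-seq, 47.3% against TATL-seq and 51.9% after subtraction.

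**Figure D2:**
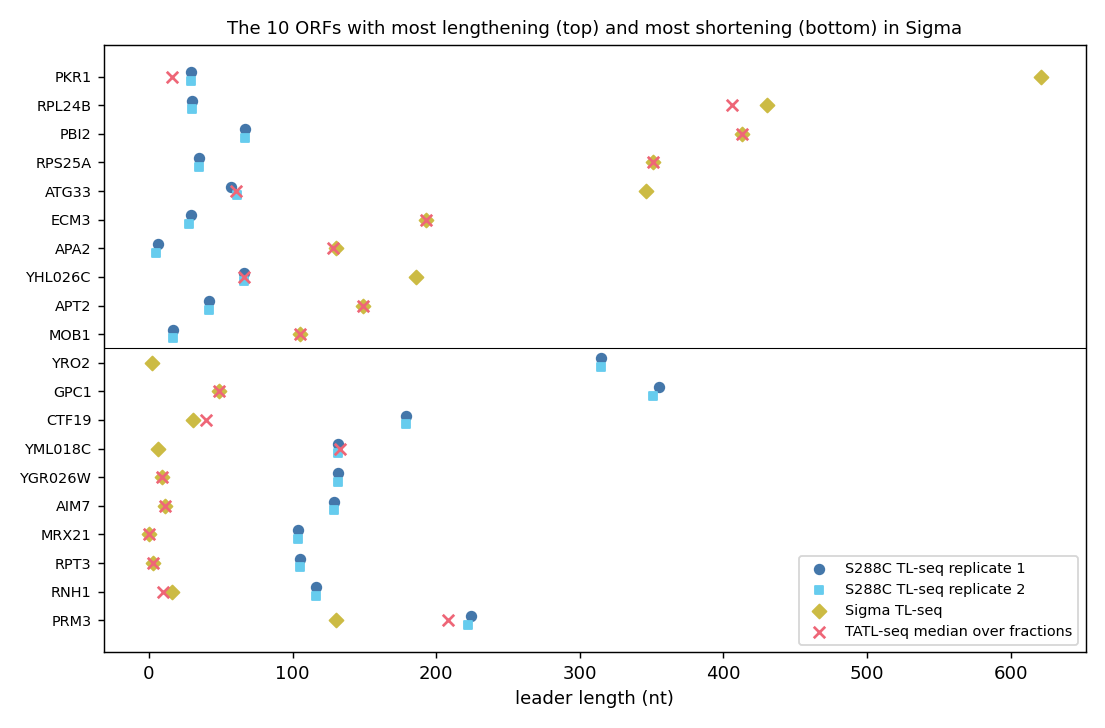
Leader length in nt of the 10 ORFs with the largest lengthening (top) and the 10 with the largest shortening (bottom) between S288C and Sigma TL-seq. Each symbol is 1 library, or the median over TATL-seq fractions (crosses; YRO2 has none); RPL24B lies at 30 nt in both S288C replicates, 430 nt in Sigma and 406 nt in TATL-seq.

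The control without pyrophosphatase asked which calls do not need removal of a cap. Ribosomal protein genes stood out among them: 26 of 132 had a call in the control (19.7%) against 4.03% of the other ORFs (odds ratio 5.84, two-sided Fisher's exact test, p = 6.91e-11, adjusted p = 1.04e-09 over 15 lists). Among ORFs called with pyrophosphatase the figures were 23 of 94, 24.5% against 8.27% (odds ratio 3.59, adjusted p = 6.56e-05, Fisher's exact test). RPL32 had 361 nt in both Sigma libraries, RPL1B 68 nt without and 59 nt with the enzyme, RPL3 1 and 16 nt, and RPL35A 3 and 45 nt. The lowest adjusted p of the other 14 lists was 0.641, for translation factors and for respiration genes with 3 of 28 called in each. These tests compare the libraries, not the treatments, and how reads shared by paired ribosomal protein genes were assigned is not given in the sources used here. Ribosomal protein genes were also called more often with pyrophosphatase, 94 of 132 against 1883 of all 4551 ORFs. Abundance of the mRNAs is unknown and was not accounted for, so these shares do not show that their ends lack caps.

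In all, 204 ORFs were called without and 1883 with pyrophosphatase, and 171 in both, 83.8% of the control calls (exact 95% interval 78.0 to 88.6), where independent lists would share 84.4 ORFs. Of the 171, 40 had the same length and 64.9% lay within 10 nt (95% Wilson interval 57.5 to 71.7). Taken alphabetically, ADD37 had 44 nt in both libraries and all 7 fractions, CAP1 24 nt in both, and BXI1 30 nt with and 28 nt without the enzyme. The cell cycle kinase gene CDC28 had 32 nt with and 1 nt without it, the peroxiredoxin gene AHP1 16 and 6 nt, AIM20 57 and 7 nt, the arginine gene ARG4 105 and 52 nt, and ARG3 20 and 22 nt. For AIM20 and ARG4 the control length matched the TATL-seq median. Over the 169 ORFs called in both Sigma libraries and a fraction, 78.1% of control calls and 83.4% of calls with pyrophosphatase lay within 10 nt of the TATL-seq median. Over the 171 shared ORFs the median difference of control from pyrophosphatase leaders was −1 nt, while over all ORFs of each library, which are different sets, the medians were 23.5 and 33 nt.

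TATL-seq and TL-seq of the S288C background were compared on 2553 ORFs. The histone genes HTA1 and HHF1 had 71 and 36 nt in TATL-seq against 74.5 and 37 nt in TL-seq, MRX16 1232 against 1231 nt, and CLN3 321 against 322 nt. Some glycolytic genes lay far apart. TDH2, for glyceraldehyde-3-phosphate dehydrogenase, had 259 nt in TATL-seq against 49 nt, and ENO1, for enolase, 319 nt in 1 fraction against 38 nt. The paralogous pyruvate decarboxylase genes PDC1 and PDC5 both had 167 nt in 1 fraction against 31 and 14.5 nt. PFK1 had 234 nt in both methods. Over all 2553 ORFs, 56.4% lay within 10 nt (95% Wilson interval 54.5 to 58.3), 345 were longer and 849 shorter in TATL-seq by at least 10 nt, and the median difference was −5 nt. These methods also differed in sequencer, and with the median difference subtracted 512 were longer and 552 shorter. On the Genome Analyzer II alone, Sigma TL-seq and TATL-seq lay within 10 nt for 81.9% of 1789 ORFs (95% Wilson interval 80.1 to 83.7), with a median difference of 0 nt.

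**Figure D3:**
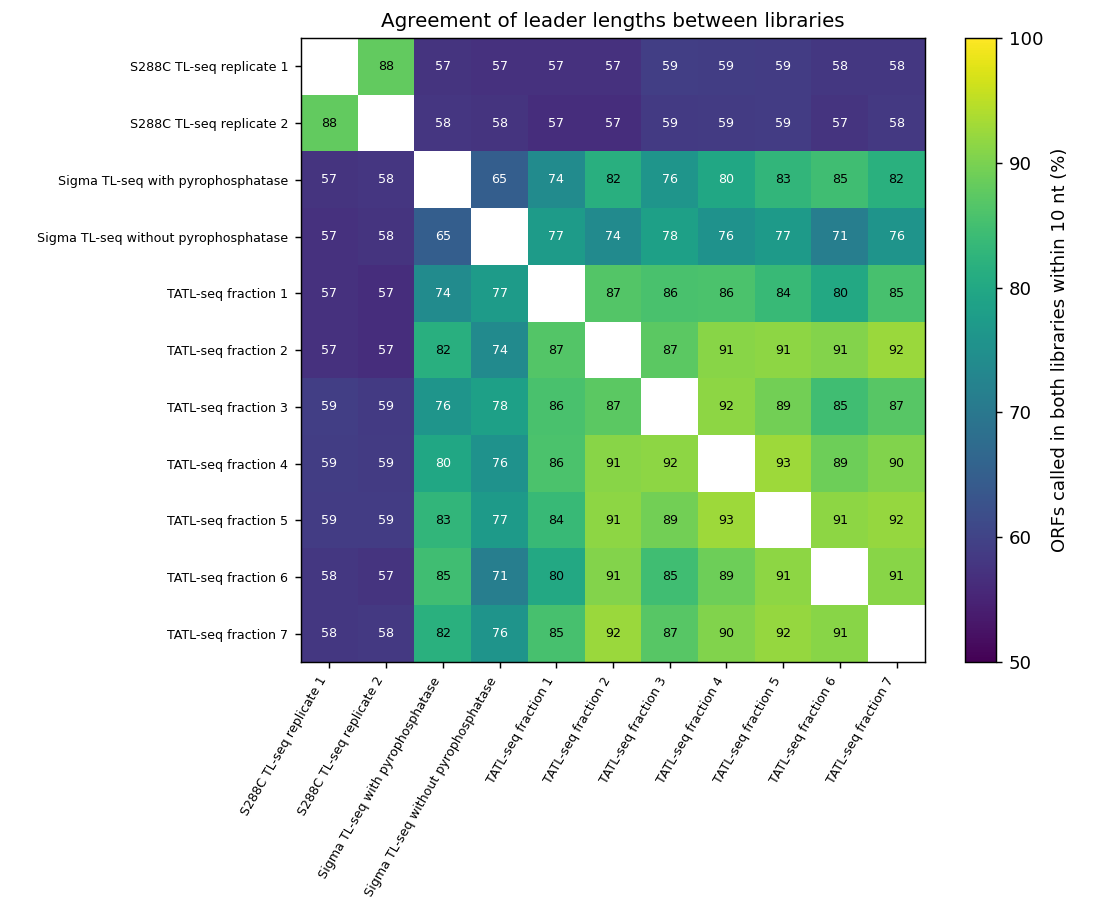
Share of ORFs, in percent of those called in both libraries, whose leader lengths lie within 10 nt, for each pair of the 11 libraries. The S288C replicates share 88.1%, pairs of an S288C TL-seq library with any other lie between 56.5% and 59.2%, and pairs of fractions between 80.2% and 92.7%.

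**Figure D4:**
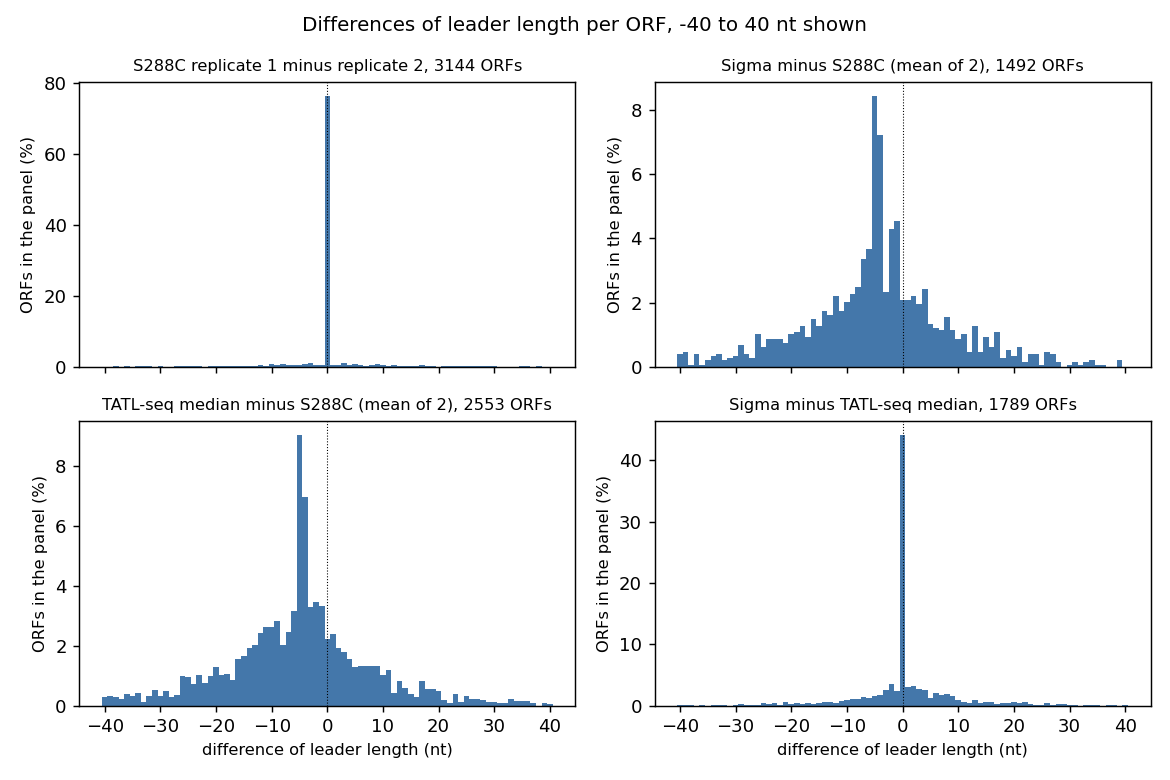
Differences of leader length per ORF in nt, shown up to 40 nt either side of 0 in bins of 1 nt, as percent of the ORFs of each panel. The S288C replicates and Sigma against the TATL-seq median peak at 0 nt, with 76.2% and 43.9% of ORFs; Sigma and TATL-seq against S288C TL-seq peak near −5 nt.

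The gradient fractions were used to ask whether leaders of a gene differ with its place in the gradient. The labels do not say which fraction was light or heavy. Among the fractions, several genes had long leaders in fraction 1 and short ones in the others: PGC1, for a phosphatidylglycerol phospholipase, had 283 nt in fraction 1 and 14 nt in the other 6; the glyoxalase gene GLO1 258 and 14 nt; the α-factor gene MF(ALPHA)2 287 nt and 38 to 41 nt; the iron transport gene FIT2 301 nt and 13 to 17 nt, with 316 nt in Sigma; and MIN7 358 nt and 16 to 21 nt. ATG33 had 346 nt in fractions 1 and 2 and 56 to 65 nt in fractions 3, 4, 6 and 7. RGI1 had 34 and 49 nt in fractions 1 and 3 and 295 nt in fractions 4, 6 and 7, and YGR161W-C 9 and 14 nt in fractions 3 and 4 and 286 nt or more in fractions 5 to 7. YHR022C had 305 nt in fractions 1 and 3, 134 nt in fraction 4 and 12 nt in fractions 5 and 7, and YGL006W-A between 738 and 1097 nt. These ORFs were picked for the widest range and do not show a general lengthening in fraction 1. Of 1576 ORFs compared, fraction 1 lay at least 10 nt above the median of the other fractions in 103 and below it in 134.

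Of 2062 ORFs called in at least 5 fractions, 638 (30.9%, 95% Wilson interval 29.0 to 33.0) had a range of 10 nt or more, 677 had the same length throughout, and the median range was 4 nt. In ribosomal proteins 27 of 109 had such a range, with RPL15B at 194 nt in fraction 1 and 29 to 36 nt in the others where it was called. Respiration genes gave 7 of 22, translation factors 4 of 14, proteasome genes 4 of 21, mitochondrial ribosomal proteins 6 of 36, genes with upstream ORFs 3 of 9, genes with earlier long leaders 3 of 6, and heat shock genes 1 of 10, histones 1 of 10 and glycolysis 1 of 9. The alternative-start genes LEU4 and ALA1 had 1 length each, and MSS11 was the 1 of 2 invasive growth genes with such a range, AGA2 the 1 of 2 a-specific genes and MF(ALPHA)2 the only α-specific gene counted. For a steady rise or fall, 795 ORFs called in all 7 fractions with more than 1 length were tested by Spearman rank correlation with exact permutation. None passed this exact permutation test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.700), and 36 had an unadjusted p under 0.05, 30 of them rising, where the ties in their lengths leave 19.2 by chance. When the fractions were reordered for all ORFs together, 36 or more was reached in a share of 0.121 of all orders (exact permutation p). A single ORF could not pass, since even a perfect trend without ties would have an adjusted p of 0.315 in this exact permutation test. At that smallest p, 7 ORFs would be needed to pass, and ties in length left 0 of the 795 able to reach it. Only 451 of them could reach an unadjusted p under 0.05 in this test. Trends in a few genes are therefore not excluded, nor are trends in ORFs whose ties kept them from passing. Each fraction was 1 library, so a range over 5 to 7 of them includes library noise, and no replicate of a fraction gives its level.

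**Figure D5:**
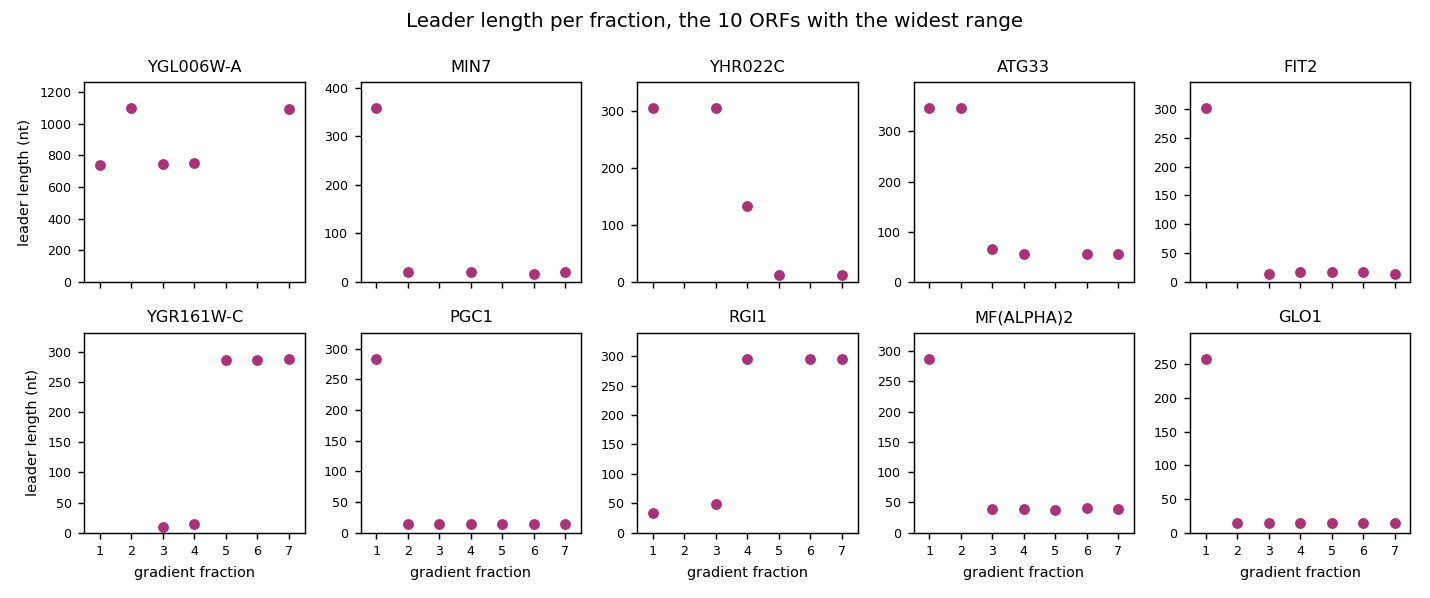
Leader length in nt by gradient fraction number for the 10 ORFs with the widest range among those called in at least 5 fractions, 1 point per library; a fraction without a point has no call. PGC1 and GLO1 have 283 and 258 nt in fraction 1 and 14 nt in fractions 2 to 7.

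Ribosomal protein genes were called about equally often in each fraction, in 82.6% (exact 95% interval 75 to 88.6) to 84.1% (76.7 to 89.9) of the 132 members called in any library, the base used for every list here. Mitochondrial ribosomal proteins were called in 75.5% to 85.7% of 49, respiration genes in 78.6% to 85.7% of 28, proteasome genes in 64.5% to 80.6% of 31, and histones in 90.9% to 100% of 11. Respiration genes were called less often in TL-seq, with 67.9% in each S288C replicate. Glycolysis genes went the other way and were called in 43.8% to 62.5% of 16, against 93.8% in each S288C TL-seq replicate, as were translation factors in 50% to 64.3% of 28, against 82.1% and 78.6%. Over all 4551 ORFs calls were also fewer in the fractions, with 45.7% to 54.6%, where the S288C replicates called 78.2% and 75.6%. Whether the lists differ from all ORFs in the size of this drop was not tested. Genes with upstream ORFs ranged from 41.2% to 64.7% of 17, heat shock genes from 36.4% to 63.6% of 22, genes with earlier long leaders from 36.4% to 63.6% of 11, alternative-start genes from 14.3% to 42.9% of 7, and invasive growth genes from 33.3% to 66.7% of 6. GCN4 had no call in any fraction. Of all 4551 ORFs, 45.7% were called in fraction 1 (exact 95% interval 44.3 to 47.2) and 53.0% to 54.6% in each other fraction. Fraction 1 alone called 171 ORFs and alone missed 302, where the other fractions alone called 42 to 94 and missed 21 to 50. ORFs called in a fraction had a median coding length, introns included, of 995 to 1059 nt, against 1366.5 to 1453.5 nt for those not called.

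Mating-type genes did not follow the label of the gradient cells. Of the a-specific genes, which cells of mating type α do not express, STE2, the α-factor receptor, had 26 nt in all 7 fractions, AGA2 51 nt in 4 fractions and 63 nt in fraction 3, MFA2 37 to 40 nt in 3, MFA1 7 nt in 2 and ASG7 35 nt in fraction 7. The α-specific MF(ALPHA)2 was called in 6 fractions and STE3 in fraction 1, at 244 nt. In S288C TL-seq no a-specific gene was called and MF(ALPHA)1, MF(ALPHA)2 and SAG1 had 55, 53 and 49 nt; Sigma, of mating type a, had MFA1, MFA2 and AGA2 and no α-specific gene. The gradient libraries are therefore called the libraries labelled BY4742, and comparisons that take them as S288C depend on that label. Of the marker genes of the growth protocol, HIS3 was called in S288C TL-seq only (24 and 6 nt), and TRP1 there (35 and 11 nt) and in fractions 5 and 7 (6 nt).

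Leaders under 12 nt made up 12.9% (95% Wilson interval 11.6 to 14.3) to 14.0% (12.6 to 15.6) of the calls of each fraction, with the highest share in fraction 1. ORFs with leaders under 12 nt in S288C were called less often in fraction 1 than other ORFs, 102 of 240 (42.5%) against 1517 of 2904 (52.2%). Of the 10 ORFs at 1 nt named above, AIM18, APC11, APM2, BET5, CIN4 and DAD4 had no call in fraction 1, and CAB5, CLF1, COQ9 and KAR9 had calls at 12, 3, 8 and 5 nt. The odds ratio was 0.676 (two-sided Fisher's exact test over ORFs, p = 0.00384, adjusted p = 0.0269 over 7 fractions). In fractions 2 to 7 the odds ratios lay between 0.808 and 0.869 and none passed Fisher's exact test (adjusted p = 0.303 in each). Whether fraction 1 differed from the other fractions was not tested. The call was lost when short meant under 20 nt (odds ratio 0.943) or under 6 nt (0.700, where fraction 4 passed instead with 0.522), or when lengths came from the TATL-seq medians (0.825), and the odds ratio was 1.04 with Sigma lengths.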

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

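The tests of sequencer batch, strain, 3′ capture, mating type, Sigma RNA and single-library noise in this part were chosen only after the results were seen. Calls on noncoding RNAs lie outside the comparisons; the control without pyrophosphatase had 0 tRNA calls and 2 snoRNA calls of 206, snR11 and snR189, which no other library called, too few to set a background for the snoRNA shares of Sigma (0.737%) and fraction 1 (0.800%). Sigma TL-seq with pyrophosphatase had calls on 14 snoRNA genes, whose trimethylated or monomethylated caps and independent promoters are known for part of the class. Fraction 1 had calls on 17 snoRNA genes, as had fraction 2, against 4 to 11 in each other fraction; snR87 lay at 166 nt in Sigma and in all 7 fractions and snR80 at 2 nt in the same libraries, and 13 of the 17 snoRNAs called in at least 2 fractions had a single length. Fraction 1 also had calls on 28 tRNA genes, 26 of them at 6 to 11 nt with a median of 8 nt, against 1 to 5 tRNA genes in each other fraction.

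S288C TL-seq leaders were longer by a median of 5 nt than those of every other library with pyrophosphatase. Start sites that differ between strains are argued against as the source of this shift over all genes, because the most common difference was −5 nt and only 2.19% of Sigma calls were identical to S288C replicate 1. The 43.9% identical to the TATL-seq median bear on strain only if the gradient cells were S288C as labelled, which the mating-type genes put in doubt. The mode of 3′ capture is argued against too, since Sigma, tailed like S288C, lay within 10 nt of the ligated TATL-seq libraries for 81.9% of ORFs and of S288C TL-seq for 58.4%. A batch of the S288C TL-seq libraries in sequencing, library making or calling could be the source, but the shares within 10 nt do not decide it. The lowest over pairs from the same sequencer, 64.9% (57.5 to 71.7), was Sigma with against Sigma without pyrophosphatase. Its interval covers the highest across sequencers, 59.2%. Among libraries with pyrophosphatase the lowest from the same sequencer was 74.2% (71.6 to 76.6), for Sigma against fraction 1. Identical calls made up at least 23.4% in pairs from the same sequencer and at most 2.89% across sequencers. These shares cannot test the cause, since the pairs across sequencers are the very pairs in which the shift was seen. S288C TL-seq also held 0 noncoding or zero-length calls of 7003 where the others held 314 of 19040, but these steps all changed together and cannot be told apart, and strain differences at single genes stay open, untested.

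Genes specific to mating type a were called in gradient libraries labelled with an α strain. A culture of mating type a could be the source, but an α-specific gene was called in 6 of 7 fractions, while MF(ALPHA)1 and SAG1, called in S288C TL-seq, were called in none. Outside the lists, MATALPHA1 at 38 nt and MATALPHA2 at 13 nt, each in a single S288C TL-seq replicate, were called in no fraction either. Both were picked after their values were seen. RNA or reads of the Sigma culture could also be the source, since 90% of the 10 a-specific calls that Sigma allows to be compared lay within 3 nt of the Sigma call, but these come from 3 genes and 60.3% of all ORF calls in the fractions lay as near, and STE2, at 26 nt in all 7 fractions, and ASG7 had no Sigma call. Any cells of mating type a should use the same start sites, so a mislabelled or mixed culture and Sigma RNA cannot be told apart without counts. No biological explanation was tested.

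Sigma leaders stood at least 10 nt apart from both S288C replicates and the TATL-seq median, on the same side, in 140 of 1285 ORFs (10.9%, 95% Wilson interval 9.31 to 12.7), among them PKR1, YHL026C and YML018C. Noise of a single library could give part of this, because fraction 1 stood apart by a like rule in 8.99% of 1379 ORFs (7.59 to 10.6). The other fractions did so in 3.32% to 5.30%. Sigma and fraction 1 share calls on 1204 ORFs only, so fraction 1 was not set against Sigma in all of the 1379. The intervals of Sigma and fraction 1 overlap and the fractions come from a single gradient, so strain differences and library noise cannot be told apart with 1 Sigma library. A difference between the strains stays open for these ORFs, and ATG33 shows the limit: its Sigma length of 346 nt was also called in fractions 1 and 2. PKR1 shows another, since its 621 nt in Sigma stood against 5 nt in the Sigma library without pyrophosphatase.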

How the results depend on the processing

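The settings with a median difference subtracted, with Sigma or TATL-seq lengths for short leaders and gene lists, with a TATL-seq call or a difference from TATL-seq required, were chosen only after the results were seen. Of S288C replicate pairs, 82.8% lay within 5 nt and 93.8% within 20 nt. ORFs that differed between Sigma and S288C numbered 904, 269 and 48 at 5, 20 and 50 nt, 712 to 725 without 1 of the replicates, 355 with TATL-seq medians as S288C, 497 after the median difference was subtracted and 140 when TATL-seq had to differ too; the share shorter in Sigma was 47.3%, 51.9% and 59.3% under the last 3. Allowing replicates 20 nt apart left 19 of the 20 named ORFs. Of control calls without pyrophosphatase, 88.5% were also called with it among ORFs of both S288C replicates, and 51.5% and 83.6% of shared ORFs lay within 5 and 20 nt. ORFs with a range over fractions numbered 345 among those called in all 7, 238 and 64 at 20 and 50 nt, and 485 to 544 with each fraction left out. Leaving out a fraction does not test the trend: with 6 fractions at least 44 ORFs with a perfect trend would be needed to pass at the smallest p, and at most 6 ORFs could reach it. With ORFs of both S288C replicates as background, fractions 1 to 7 called 51.5%, 59.0%, 61.6%, 60.8%, 60.4%, 60.6% and 61.8%. TL-seq and TATL-seq lay within 10 nt for 58.4% with the longest call, 60.5% with fraction 3, which had the most calls, and 61.0% after subtraction, and within 20 nt for 79.1%. The rarer calling in fraction 1 of ORFs with short leaders did not pass Fisher's exact test at under 20 nt (odds ratio 0.943, adjusted p = 0.661), under 6 nt (0.700, 0.121, where fraction 4 passed) and with TATL-seq lengths (0.825, 0.186), reversed with Sigma lengths (1.04, 0.931), and passed without 1 of the S288C replicates (0.668 to 0.707, where 4 fractions passed without replicate 2). The cause was not tested, except that fewer ORFs are under 6 nt (84). All 14 alternatives for gene lists left each list on its side of the threshold. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Upstream AUGs, count tests and minimums of reads were not run, no negative length occurs, and depth, which is unknown, limits every statement on missing calls.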

Other observations

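Of the tests in this part, that of fraction 1 against fraction 7 was chosen only after the result was seen; that of neighbouring genes was set beforehand. Among ORFs that differ in length between libraries, RPL24B and GPC1 are adjacent and divergent, and they differed in opposite directions: RPL24B was 30 nt in S288C TL-seq and 399 to 430 nt in the fractions, GPC1 351 and 355 nt in S288C TL-seq and 45 to 49 nt in the fractions. RPS8B and RPL32 had long leaders in S288C TL-seq and in Sigma, of 378 and 366 nt and of 376 and 361 nt.

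Yeast genes with a divergent upstream neighbour share their promoter region with it, so their leaders may differ from those of genes with a tandem neighbour. Over S288C TL-seq, 1675 ORFs with a divergent neighbour in assembly R64 had a median leader of 40 nt and 1466 with a tandem neighbour 44 nt (two-sided permutation test over genes, p = 0.0186). The difference is small beside the spread of leaders, whose quartiles lie at 24.5 and 70 nt.

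Another hypothesis is that mRNAs called only at 1 end of the gradient differ in their leaders. The 273 ORFs called in fraction 1 and not in fraction 7 had a median S288C leader of 45 nt, and the 598 called in fraction 7 and not in fraction 1 had 41 nt (permutation test, p = 0.0142). Leaders of 100 nt or more made up 25.6% and 13.2% of these sets. In fraction 1, 20.8% of all calls were 100 nt or longer against 13.5% to 15.4% in the other fractions. Over all ORFs, though, those called in fraction 1 had a shorter median S288C leader than those not called, 41 against 42.5 nt, as in every other fraction (39 to 40 against 44 to 47 nt), and fraction 1 is 1 library whose place in the gradient is not stated.

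Where fraction 6 lay at least 10 nt from the median of the other fractions, its length was within 2 nt of the Sigma leader in 42 of 108 ORFs (38.9%), against 85 of 603 (14.1%) for the other fractions pooled, where an ORF can count more than once; a Fisher's exact test first made on these counts is not used, since fraction 6 was picked for this share. The single other fractions ranged from 7.32% in fraction 4 to 26.4% in fraction 5, whose exact interval (16.7 to 38.1) overlaps that of fraction 6 (29.7 to 48.7). RPS16A, at 76 nt in fraction 6 and in Sigma and 17 nt in the other 6 fractions, and COX7, at 29 nt in both and 44 nt in the other 6, are examples chosen after their values were seen.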
